A study of Mus musculus with 30 samples.

How the data were processed

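The study measured messenger RNA in single cells of whole mouse hearts by Drop-seq at 5 ages from E16.5 to P7, with 6 hearts per age. The authors deposited a table of raw UMI counts, whole numbers per gene and cell, and a table of cell annotations that gives per cell the heart, litter, sex, flowcell, cluster, label, doublet score, UMI counts, gene counts and the percent of mitochondrial UMIs. The deposited tables hold 67330 cells of 36 hearts and 23249 genes, and the summed counts of each cell used here equal the deposited total. Per the submitters' processing notes, bcl2fastq 2.17, kallisto, bustools and genome build GRCm38 were used, with roles and order not given in the sources used here. The deposited cells have at least 500 genes (at most 3811), between 615 and 10000 UMIs and at most 15% mitochondrial UMIs. The deposited doublet column marks 0 of these cells, the highest deposited doublet score (scrublet) is 0.249, and no doublet caller was run, so doublets stay open. The share of blank or summary entries in the count table was 0.

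The 52209 cells of the 30 hearts with ages E16.5 to P7 were analysed, and the 15121 cell columns of 6 further hearts were not analysed here. The 19 deposited cell labels were gathered into 11 classes, and for 6 of them the UMI counts were summed per heart, so that the heart is the sample in each test. Each class needed at least 10 cells in a heart. The top genes of each of the 36 deposited clusters were checked against marker genes fixed beforehand. Depth per heart ranged from 2336517 to 9056497 UMIs, and a median cell held 2315 UMIs of 1138 genes. Gene names were matched to the GENCODE vM21 annotation of GRCm38, in which 22773 of the 23249 names have 1 location, and the authors' annotation release may be another one.

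Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, its default filter on low counts) on all 30 hearts with terms for age and sex, and called at an adjusted p (Benjamini-Hochberg) below 0.05. P7 was compared with E16.5 in 6 classes, and each neighbouring pair of ages in cardiomyocytes, fibroblasts and endothelial cells. Males were compared with females, and the difference of the age change between the sexes was tested in cardiomyocytes. Log2 changes are given with their SE, later age minus earlier age, from the edgeR fit. For genes with 0 counts in a group a lower bound is given against a floor of 3 counts over the group, and with 1 to 3 counts the ratio with its exact 95% counting interval. These cover counting error only. Shares of cells were tested per heart with 2-sided exact permutation tests over all 924 regroupings of 6 against 6. These count littermates as independent hearts. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, and again with the correlation estimated from the data and with fry, which asks whether a set's genes move on balance one way. A list described as having risen or fallen passed with the preset correlation. The list counts are of members past the threshold over all genes tested, with the count adjusted over the list alone beside it. A gene counted as carried over when its mean was at least 5 times higher in another class.

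The comparisons, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. Named genes have an adjusted p below 0.05, a mean of at least 50 CPM in the higher group, hearts of the 2 groups that do not overlap, and are not carried over. Unnamed gene models, hemoglobin, mitochondrial and ribosomal protein genes were left out. The 10 largest changes each way were named for P7 against E16.5 in the 3 largest classes and the 5 largest each way in the other age comparisons, with up to 4 members of smallest p from each list discussed and the sex genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty. The other genes of the sex comparison, the genes that lead clusters, and the shared genes were named after their values were seen.

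Alternatives tried were DESeq2 1.42.0, RLE scaling, no filter, no sex term, flowcell or replicate number as a block, sums per litter, limma-voom with litter as a random block, only cells with at least 1000 UMIs, at least 30 cells per heart, no carried-over genes, only the hearts of the 2 ages compared, and leaving out each heart in turn. For shares they were a logit scale, litter means, flowcell or replicate blocks, blood cells left out, and deeper cells. Chosen after seeing the data were fits to single labels, leaving out a fibroblast cluster, all P0 hearts, P0 litter 12 or each P0 replicate, and the sex of the deposited cell table. The procedure was tested on simulated data with chosen genes changed 2-fold or 4-fold. Counts were drawn from each gene's mean over all hearts, the library sizes and the dispersion trend. No other effect of age, sex or litter was put in, so the setting is easier than the data. Of the 4-fold changes, edgeR recovered 98.0% in cardiomyocytes, 100% in fibroblasts, 98.0% in endothelial cells, 95.8% in epicardial cells, 99.0% in mural cells and 97.9% in macrophages, and of the 2-fold changes 60.4%, 74.5%, 73.0%, 44.6%, 64.6% and 54.3%. False calls were 4.91%, 6.59%, 7.10%, 2.22%, 1.25% and 2.70% of the edgeR calls in these classes at P7 against E16.5. With DESeq2 they were at most 9.09%, in endothelial cells. Calculations used R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.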

Results

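Single cells from 30 whole mouse hearts of the inbred strain C57Bl/6NJ were measured by Drop-seq, a droplet method that counts messenger RNA molecules per cell by their molecular barcodes (UMIs). The hearts were collected at 5 ages around birth, E16.5, E18.5, P0, P4 and P7, with 6 hearts at each age. They gave 52209 cells with 150642900 UMIs, at a median of 2315 UMIs and 1138 genes per cell. The mean total per heart was 5.80e+06 UMIs at E16.5 (range 4446910 to 7350445), 4.60e+06 at E18.5 (2412811 to 6150572), 4.31e+06 at P0 (2336517 to 5380131), 5.16e+06 at P4 (4147609 to 6216096) and 5.23e+06 at P7 (2388393 to 9056497). The P7 and E16.5 totals did not differ beyond the spread between hearts (2-sided exact permutation p = 0.593). Median UMIs per cell averaged 2918.6 at E16.5, 2810.4 at E18.5, 2036.8 at P0, 2456.7 at P4 and 2220.1 at P7 (P7 against E16.5, exact p = 0.249), and median genes per cell 1369.7, 1236.8, 1017.3, 1212.2 and 1126.8 (exact p = 0.247). The median share of mitochondrial UMIs per cell averaged 3.27%, 3.48%, 6.19%, 3.71% and 3.98% at the 5 ages in order.

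The deposited cell labels were gathered into 11 classes, of which cardiomyocytes (19917 cells), fibroblasts (15737), endothelial cells (8864), mural cells (3418), macrophages (1990) and epicardial cells (1017) were tested for gene changes. Several labels did not match the genes that led their cluster. Cells labelled CCR2-high macrophages (448 cells) were led by Gzma, Trbc1, Cd8b1 and Cd3e, which are genes of T and natural killer lymphocytes. Cells labelled T cells (53 cells) were led by the mast cell genes Cpa3, Tpsb2, Cma1 and Mcpt4. A fibroblast cluster of 1623 cells had Pdgfrb, Notch3 and Foxs1 among its leading genes. Its Rgs5 (1202 CPM) and Pdgfrb (183) lay between the other fibroblasts (167 and 49.7) and mural cells (5361 and 277). Its Dcn (2907), Tcf21 (514) and Pdgfra (124) lay far above mural cells (312, 79.9 and 20.5), and its Myh11 far below (7.54 against 1119). Its fibroblast label is therefore not shown to be wrong. This cluster held 7.83% of the fibroblasts at E16.5, 17.6% at P0 and 5.59% at P7. Deposited names are used throughout.

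The first comparison asks how the make-up of the heart changes between the late fetal stage and the end of the first week of life. Cardiomyocytes, the contracting muscle cells, made up 48.1% ± 4.43 of the cells at E16.5 and 15.1% ± 7.58 at P7 (mean ± SD, n = 6 hearts at each age). Fibroblasts, the matrix-producing stromal cells, went the other way, from 16.9% ± 1.85 to 49.7% ± 5.39. Macrophages rose from 1.79% ± 0.391 to 7.09% ± 0.957 (cells labelled CCR2-low alone from 1.30% to 5.58%). Valvular interstitial cells fell from 5.10% ± 2.45 to 0.531% ± 0.379. In these 4 classes every heart of one age lay beyond every heart of the other, which gave the smallest 2-sided exact permutation p that regrouping 6 and 6 hearts allows (0.00216, adjusted p = 0.00397 over 11 classes). The hearts of these ages came from 7 litters, each of a single age. The test treats littermates as independent, so its p does not cover differences between litters. The same p was reached by the rise of B cells from 0 of 11237 cells, which allows a share of up to 0.0267%, to 0.629% ± 0.359, and of cells labelled melanocytes from 0.172% to 0.411%. Cells labelled T cells fell from 0.134% to 0.0357% (exact p = 0.0303, adjusted p = 0.0476), which did not pass on the logit scale (adjusted p = 0.0873). Endothelial cells (17.6% and 17.2%, exact p = 0.797), mural cells (7.77% and 7.63%, exact p = 0.916) and epicardial cells (2.24% and 1.73%, exact p = 0.0736) did not differ beyond the spread between hearts. Neuronal cells were 0.118% at E16.5 and 0 of 11518 cells at P7, which allows up to 0.0260% (adjusted p = 0.0833). With flowcell as a block the changes of B cells and of cells labelled melanocytes and T cells no longer passed (adjusted p = 0.245 for each), and epicardial cells passed (adjusted p = 0.00209). Shares are of captured cells, so a change in one class moves the others.

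**Figure D1:**
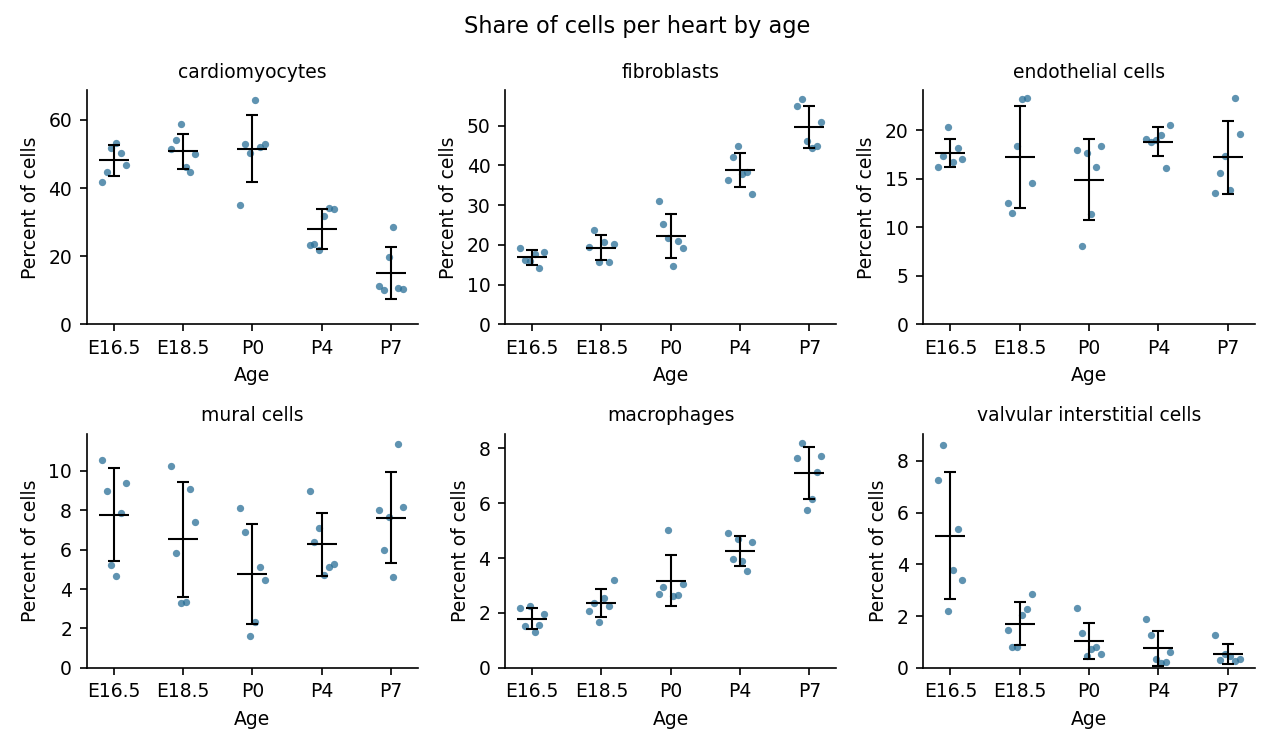
Share of cells per heart (percent, vertical axis) against age for 6 cell classes, with points for single hearts and bars for mean ± SD (n = 6 hearts per age). Cardiomyocytes stayed near 50% of the cells until P0 and averaged 15.1% at P7, while fibroblasts averaged 22.1% at P0 and 49.7% at P7.

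Most of this shift fell after birth. The cardiomyocyte share was 51.5% ± 9.81 at P0 and 28.1% ± 5.82 at P4, and the fibroblast share 22.1% ± 5.52 and 38.8% ± 4.28, without overlap between hearts (exact p = 0.00216, adjusted p = 0.0238 over all classes and steps). From P4 to P7 fibroblasts rose again (adjusted p = 0.0408) and macrophages rose from 4.26% to 7.09% (adjusted p = 0.0238), and the cardiomyocyte step missed the threshold (adjusted p = 0.0833). Valvular interstitial cells fell at the first step, from 5.10% at E16.5 to 1.71% at E18.5 (adjusted p = 0.0408). B cells were first captured at P0 (0.116%, adjusted p = 0.0238) and averaged 0.492% at P4 (adjusted p = 0.0381), a mean that rests on P4 replicate 1 (1.43%), since the other 5 hearts had 0.128% to 0.469%. Within the muscle, ventricular cells fell from 35.7% to 6.63% of all cells between E16.5 and P7 and trabecular cells, which line the fetal chambers, from 1.63% to 0.0357%. Cells labelled atrial cardiomyocytes 1 fell from 8.65% to 2.48%, and those labelled atrial cardiomyocytes 2 rose from 2.14% to 5.95%, so that they were 4.35% of the cardiomyocytes at E16.5 and 40.8% at P7. The fall of atrial cardiomyocytes 1 was not steady, with 5.67% at E18.5, 8.95% at P0 and 3.77% at P4 (adjusted p = 0.0165 at each of these 3 steps). Within the endothelium, endocardial cells, the inner lining of the chambers, fell from 11.5% to 3.35% and vascular endothelial cells rose from 3.41% to 9.59%. Each of these label changes between E16.5 and P7 had an exact p of 0.00216 (adjusted p = 0.00343 over 19 labels). The classes of cardiomyocytes and endothelial cells therefore differ in composition between ages, and results for single labels are given beside several of theirs.

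In cardiomyocytes the comparison of P7 with E16.5 asks which genes change as fetal muscle matures, and 1578 genes were higher and 1617 lower of 10973 tested. The largest falls included Myh7, the slow beta myosin heavy chain of the fetal ventricle (log2 change -6.19, SE 0.34, adjusted p = 1.66e-16; 5490 CPM at E16.5 and 73.5 at P7). Hey2, a Notch target of the ventricular wall, fell by 3.89 (SE 0.26), and the lactate exporter Slc16a3 and the glucose transporter Slc2a1 fell by 3.29 (SE 0.39) and 2.76 (SE 0.31). Gtsf1 of the small RNA pathway of germ cells fell by 4.80, the tubulin Tubb2b by 3.23, Bex1 by 2.95 and the imprinted growth inhibitor Grb10 by 2.56, and the incretin receptor Gipr and the acyl-CoA synthetase Acsl3 fell too. Among the genes that rose were the actin-binding intercalated disc protein Xirp2 (4.12, SE 0.27), the fatty acid desaturase Scd4 (5.44, SE 0.25), the Myh7 antisense transcript Mhrt (4.66, SE 0.31), the kinase Mylk4 (4.59, SE 0.31), Tppp3 (4.02, SE 0.30) and the growth factor Bmp10 (4.19, SE 0.33). Mlana rose by 7.01 (SE 0.34), Sbk3 by 5.87 (SE 0.40) and Pdzrn4 by 3.73 (SE 0.31). The matrix proteoglycan Podn had 342 UMIs at P7 and 1 at E16.5, a ratio of 1197 with a counting interval of 213 to 47428. For each named gene all 6 hearts of one age lay beyond all 6 of the other. In build GRCm38, Myh7 (ENSMUSG00000053093.16) lies on chromosome 14 on the strand opposite to Mhrt (ENSMUSG00000097652.2), and their annotated spans overlap. The sources used here do not say whether the counts tell the strands apart.

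By gene list, muscle maturation and fatty acid use rose and proliferation fell with the preset correlation, and the calls of these 4 lists were lost with an estimated correlation. Of the 20 measured cardiac isoforms that rise with maturation, 13 rose and 2 fell (15 and 2 adjusted over the list alone), with the M-band protein Myom2 (2.80), the adult alpha myosin Myh6 (2.35), the calcium pump Atp2a2 (2.13) and the oxygen store Mb (3.10) among them. Of 29 genes of fatty acid uptake and oxidation, 21 rose (23 adjusted over the list alone), among them the lipid droplet protein Plin5 (5.00) and Decr1 (1.85). With an estimated correlation these 2 lists had adjusted p = 0.0638 and adjusted p = 0.0985. Calcium handling and ion channels rose in 15 of 22 members and fell in 1 (16 and 1 adjusted over the list alone), as for the calcium release channel Ryr2 (1.61), and this call held with an estimated correlation (adjusted p = 0.00125). Glycolysis fell in 10 of 22 members and rose in 4 (12 and 4 adjusted over the list alone; adjusted p = 0.262 with an estimated correlation), with Pgam1 at -2.09 and Aldoc at -3.07 against Pfkm at 1.23. Of the S phase genes 20 of 30 fell (24 adjusted over the list alone; adjusted p = 0.146 with an estimated correlation), as did 26 of 35 genes of G2 and M phase (26 adjusted over the list alone; adjusted p = 0.288 with an estimated correlation), for example Mcm3 (-1.22) and Hmgb2 (-1.70). The imprinted growth network fell in 10 of 16 members (11 fell and 1 rose adjusted over the list alone; adjusted p = 0.00125 with an estimated correlation), as for Grb10 (-2.56) and Igf2r (-1.91), and 10 of its 16 members were at least 5-fold more abundant in another class. Cytosolic ribosomal proteins fell in 55 of 77 members (68 adjusted over the list alone; adjusted p = 0.347 with an estimated correlation), with a median of -0.61 whose sign held under RLE scaling and without the filter.

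The change in the mix of labels bears on several of these values. In ventricular cells alone 1324 genes were higher and 1388 lower of 9884. Of the 2914 class calls tested there, 94.0% had the same direction, and 1681 also passed in that direction. Ventricular cells are part of the class, so the shared direction is in part built in. Xirp2 (5.24), Myh7 (-5.80), Hey2 (-3.26), Slc16a3 (-4.37), Slc2a1 (-4.16) and Grb10 (-2.33) passed there too, as did Scd4, Mhrt, Mylk4, Tppp3, Gtsf1, Tubb2b, Gipr, Bex1 and Acsl3. Bmp10 reversed to -2.73 in ventricular cells (adjusted p = 0.0257). Podn, Mlana, Sbk3 and Pdzrn4 had too few counts to be tested there, and they rose in cells labelled atrial cardiomyocytes 2, for example Mlana by 4.71. In ventricular cells 17 of 20 maturation isoforms, 28 of 29 fatty acid genes and 55 of 69 nuclear oxidative phosphorylation genes rose (1 of the latter fell), against 9 of 69 in the whole class, where that list's call was lost with an estimated correlation (adjusted p = 0.598). Calcium handling and ion channels rose in 9 of 22 and fell in 1 there (median 0.49, against 0.86 in the class). Markers of other classes rose there too, those of fibroblasts in 7 of 7 (median 2.67), those of endothelial cells in 4 of 5 (median 1.80) and fibrillar collagens and matrix in 16 of 24 (1 fell, median 1.55). Ribosomal proteins fell in 13 of 77 members in ventricular cells, and the cell cycle lists fell in 19 of 30 and 29 of 35. With sequencing flowcell as a block the class counts were 817 higher and 816 lower.

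From E16.5 to E18.5 cardiomyocytes changed least before birth, with 92 genes higher and 29 lower. The mitochondrial creatine kinase Ckmt2 rose by 1.82 (SE 0.27, adjusted p = 1.19e-04), Myom2 by 1.39 (SE 0.16), Ptgds by 1.30, the caveolar protein Cavin4 by 1.15 and Nme2 by 1.15. The slow skeletal troponin Tnnt1 fell by 1.11 (SE 0.16), and Lama4 and Armh4 fell by 0.87 each. In the list of isoforms that rise with maturation 6 of 20 members rose (14 adjusted over the list alone; adjusted p = 0.00876 with an estimated correlation), Cox8b (0.99) among them. In ventricular cells alone 97 genes were higher and 21 lower, Tnnt1 fell by 1.34 and 9 of these 20 isoforms rose, whereas Tnnt1 was 0.52 in cells labelled atrial cardiomyocytes 2 (adjusted p = 0.753). The count in the class ranged widely with the processing, from 30 genes with sums per litter to 354 without the filter.

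At birth 1599 cardiomyocyte genes were higher and 1537 lower at P0 than at E18.5, the most of the 4 steps, though not with flowcell as a block (907, against 980 from P0 to P4). Plin5 rose by 3.96 (SE 0.33), Mhrt by 3.57, the acyl-CoA thioesterase Acot1 by 2.87 and Sbk2 by 2.75. Slc16a3 fell by 4.23 (SE 0.38) and the mitotic genes Cdc20, Cdca8, Cdk1 and Ube2c fell by 2.95, 2.60, 2.48 and 2.44. All 30 S phase genes and all 35 genes of G2 and M phase fell (30 and 35 adjusted over the list alone), and these calls held with an estimated correlation (adjusted p = 0.00436 and adjusted p = 0.0234). Fatty acid genes rose in 24 of 29 members (24 adjusted over the list alone; adjusted p = 0.0147 with an estimated correlation), for example Acsl1 (1.94) and Decr1 (1.66). Glycolysis fell in 15 of 22 members and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 0.00785 with an estimated correlation), with Pgam1 at -2.18 and Pgk1 at -1.39. The hypoxia response list fell in 12 of 20 members and rose in 2 (13 and 2 adjusted over the list alone; adjusted p = 0.0147 with an estimated correlation), as for Mif (-1.97) and Ldha (-1.31). Calcium handling rose in 12 of 22 (12 adjusted over the list alone; adjusted p = 0.00436 with an estimated correlation), and ribosomal proteins fell in 60 of 77 (70 adjusted over the list alone; adjusted p = 0.203 with an estimated correlation; median -0.64, of the same sign under RLE scaling and without the filter). The median share of mitochondrial UMIs in cardiomyocytes was 9.44% at P0 and 5.75% at E18.5. In ventricular cells alone 1249 genes were higher and 1070 lower. Of the 2971 class calls tested there, 99.8% had the same direction, and 2137 also passed in that direction. Ventricular cells are part of the class, so the shared direction is in part built in. Immediate early genes that tissue dissociation also induces rose there in 6 of 22 members and fell in 0 (median 0.49). From P0 to P4 they rose in 0 and fell in 5 (median -0.35). With flowcell as a block 373 genes were higher and 534 lower, and sums per litter gave 2005 changed genes.

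From P0 to P4 part of this pattern ran backwards, with 971 genes higher and 933 lower. Nmrk2, a nicotinamide riboside kinase of muscle, rose by 5.25 (SE 0.38; 526 CPM at P4 and 13.5 at P0), Mlana by 2.72, and Ube2c, Cdca8 and Cdk1 by 2.65, 2.54 and 2.54. Myh7 fell by 2.63 (SE 0.29), Ppip5k2 by 1.66 and the noncoding Zfas1 by 1.60. Atcayos, a transcript annotated on the strand opposite to Nmrk2 with an overlapping span, fell by 2.21. S phase genes rose in 26 of 30 members (27 adjusted over the list alone; adjusted p = 0.00730 with an estimated correlation) and all 35 genes of G2 and M phase rose (35 adjusted over the list alone; adjusted p = 0.0303 with an estimated correlation). Glycolysis rose in 9 of 22 (10 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation), for example Pgk1 (0.74) and Ldha (0.76). Fetal cardiac isoforms and stress genes rose in 9 of 17 members and fell in 1 (9 and 3 adjusted over the list alone; adjusted p = 0.214 with an estimated correlation), with Ankrd1 at 2.04 and Acta1 at 2.28 against Myh7. In ventricular cells alone 810 genes were higher and 863 lower, with 25 of 30 S phase genes, all 35 genes of G2 and M phase and 9 of 22 glycolysis genes higher, but 5 of 16 fetal isoforms and stress genes higher and 1 lower (median 0.35, against 0.79 in the class). Sums per litter gave 1089 changed genes and flowcell as a block 980. The P0 hearts stand in this step and in the one before it, so errors in them push both in opposite directions.

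From P4 to P7 180 genes were higher and 220 lower in cardiomyocytes. Nmrk2 fell by 2.89 (SE 0.34, adjusted p = 1.09e-06), the tubulins Tubb2b and Tubb2a fell by 2.46 and 1.80, the cytokine receptor Tnfrsf12a by 1.87 and Bex1 by 1.70, and all 5 passed in ventricular cells too. Podn rose by 2.24, Sbk3 by 1.79, Sbk2 by 1.16 and the muscle ubiquitin ligase Fbxo32 by 1.18, the last also in ventricular cells (1.66). Sort1 rose by 1.16 in the class and was 0.08 in ventricular cells (adjusted p = 0.974). S phase genes fell in 5 of 30 members and genes of G2 and M phase in 4 of 35 (10 and 9 adjusted over the list alone; adjusted p = 0.359 and adjusted p = 0.450 with an estimated correlation). Fatty acid genes fell in 3 of 29 and nuclear oxidative phosphorylation genes in 2 of 69 (12 and 22 adjusted over the list alone; adjusted p = 0.431 and adjusted p = 0.450 with an estimated correlation), among them Hadhb (-0.77) and Sdha (-0.54). In ventricular cells alone 0 of 29 and 0 of 69 members of these 2 lists fell (medians -0.05 and -0.17), 3 of 30 S phase genes fell, and 16 of 35 genes of G2 and M phase fell. The total was 97 genes with sums per litter and 615 without the filter.

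**Figure D2:**
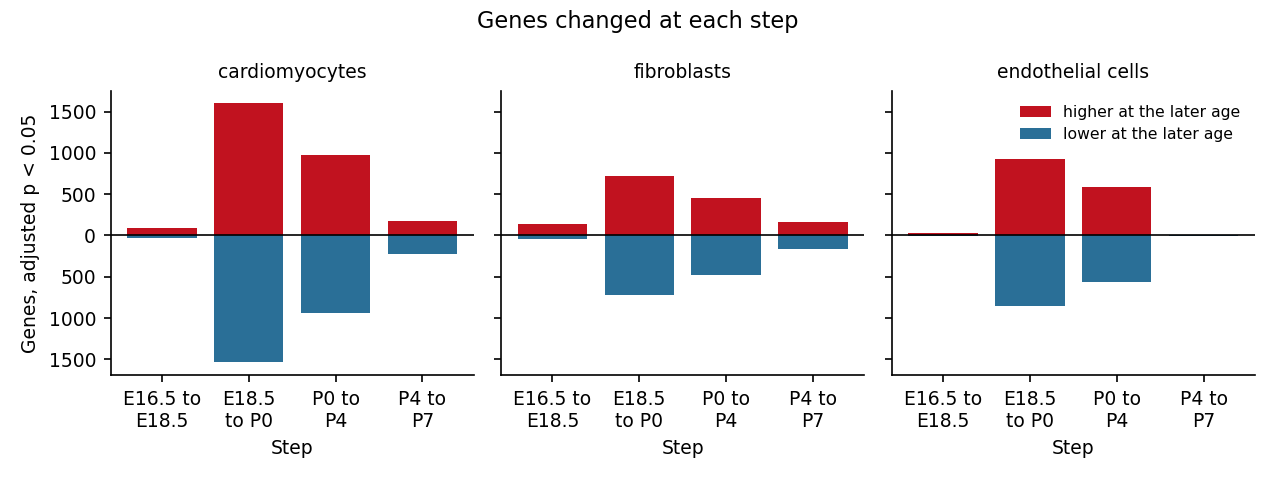
Number of genes higher (upward bars) or lower (downward bars) at each step between neighbouring ages in cardiomyocytes, fibroblasts and endothelial cells, at an edgeR adjusted p below 0.05 with 6 hearts per age. In these fits, which have no flowcell block, the step from E18.5 to P0 is the tallest in each class, with 1599 genes higher and 1537 lower in cardiomyocytes.

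In fibroblasts 1363 genes were higher and 1318 lower of 9935 tested at P7 than at E16.5. The oncofetal chromatin protein Hmga2 fell by 4.56 (SE 0.41), the imprinted preadipocyte factor Dlk1 by 3.56 (SE 0.34), the fetal mRNA-binding protein Igf2bp1 by 3.31 (SE 0.21), the amino acid transporter Slc38a5 by 3.32, Asb4 by 2.73, the imprinted Zdbf2 by 2.72 and the adhesion molecule Ncam1 by 2.59. Pla2g12a, Mpp6 and Celf4 fell by 2.55, 2.41 and 2.39. The procollagen enhancer Pcolce2 rose by 5.10 (SE 0.36), Pi16, a marker of stromal progenitors, by 5.26 (SE 0.37, adjusted p = 4.14e-14; 8.84 and 298 CPM), the guidance factor Sema3c by 4.80, Pamr1 by 5.09, the leptin receptor Lepr by 4.43 and the extracellular superoxide dismutase Sod3 by 4.43 (SE 0.24). The cytokine Il6 rose by 6.20 (SE 0.65) and osteoprotegerin, Tnfrsf11b, by 5.52 (SE 0.62). The metalloreductase Steap3 had 1004 UMIs at P7 and 1 at E16.5, a ratio of 369 with a counting interval of 66.1 to 14593. Angiotensin-converting enzyme, Ace, had 1066 and 3, a ratio of 131 with an interval of 44.6 to 634.

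Fibroblast matrix genes rose together, with 23 of 29 members of fibrillar collagens and matrix higher and 2 lower (23 and 2 adjusted over the list alone; adjusted p = 0.00416 with an estimated correlation), as for Dpt (1.85) and Fbln2 (1.71). Basement membrane genes rose in 11 of 14 and fell in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.0221 with an estimated correlation), with Lama2 at 2.73 and Hspg2 at 2.05. The imprinted growth network fell in 11 of 18 members (12 adjusted over the list alone; adjusted p = 0.00382 with an estimated correlation), H19 at -2.10, Igf2 at -1.92 and Peg10 at -1.84 among them. S phase and G2 and M phase fell in 24 of 30 and 28 of 35 (25 and 30 adjusted over the list alone; adjusted p = 0.157 and adjusted p = 0.261 with an estimated correlation). Glycolysis fell in 9 of 20 and rose in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.261 with an estimated correlation), Slc16a3 at -1.72. Ribosomal proteins fell in 45 of 77 (66 adjusted over the list alone; adjusted p = 0.307 with an estimated correlation; median -0.54, of the same sign under RLE scaling and without the filter). Immediate early genes that tissue dissociation also induces rose in 18 of 22 members (18 adjusted over the list alone; adjusted p = 0.00743 with an estimated correlation), with Klf4 at 2.13, Jun at 1.79 and Dusp1 at 1.65. Antigen presentation and interferon genes rose in 12 of 22 (13 adjusted over the list alone; adjusted p = 0.131 with an estimated correlation), but 14 of the 22 were at least 5-fold more abundant in another class. With flowcell as a block 853 genes were higher and 565 lower.

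Fibroblasts had 142 genes higher and 41 lower at E18.5 than at E16.5. Mfap5 rose by 1.90 (SE 0.24, adjusted p = 4.20e-06), the chemokine Cxcl1 by 1.83, the plasminogen-binding Clec3b by 1.76, the copper carrier Cp by 1.76 and lipoprotein lipase, Lpl, by 1.75. Cdh13 fell by 1.92 (SE 0.26), Casp6 by 1.10, Ggta1 by 0.93, Meis2 by 0.80 and Cdk14 by 0.76. Matrix genes rose in 7 of 29 members (11 rose and 1 fell adjusted over the list alone; adjusted p = 0.0509 with an estimated correlation). Interferon genes rose in 8 of 22 (15 adjusted over the list alone; adjusted p = 0.0530 with an estimated correlation), and 15 of the 22 were at least 5-fold more abundant elsewhere. Sums per litter gave 70 changed genes at this step and DESeq2 290.

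At P0 723 genes were higher and 717 lower in fibroblasts than at E18.5. Igfbp3, which binds insulin-like growth factors, rose by 2.23 (SE 0.39), Lepr by 2.10 (SE 0.25, adjusted p = 6.65e-07), Cp by 1.96, the lipase inhibitor Angptl4 by 1.92 and Egr2 by 1.55. Fdps of the isoprenoid pathway fell by 2.84 (SE 0.39), Slc16a3 by 2.75 (SE 0.25), Dlk1 by 1.80, the mitochondrial folate enzyme Mthfd2 by 1.70 and the collagen chaperone Serpinh1 by 1.41. Glycolysis fell in 10 of 20 members (11 adjusted over the list alone; adjusted p = 0.0332 with an estimated correlation), for example Gapdh (-1.25) and Pkm (-0.92). The hypoxia response fell in 9 of 20 and rose in 1 (10 and 1 adjusted over the list alone; adjusted p = 0.0332 with an estimated correlation), P4ha1 at -1.06. S phase fell in 8 of 30 and G2 and M phase in 12 of 35 (18 and 14 adjusted over the list alone; adjusted p = 0.205 and adjusted p = 0.358 with an estimated correlation), and immediate early genes rose in 12 of 22 (13 adjusted over the list alone; adjusted p = 0.0759 with an estimated correlation), as for Fos (1.42) and Jun (1.27). The count of changed genes rests in part on P0 replicate 1, without which it was 778, and it was 170 with flowcell as a block (648 from P0 to P4) and 545 with sums per litter.

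From P0 to P4 457 fibroblast genes were higher and 478 lower. The collagen-related secreted protein Cthrc1 rose by 2.14 (SE 0.18, adjusted p = 2.41e-10), Pi16 by 2.05, Sema3c by 1.84, Pamr1 by 1.72 and Mfap5 by 1.57. Serpina3g fell by 3.67 (SE 0.65), Igfbp3 by 2.51, Cyp1b1 by 2.29, the ferritin receptor Scara5 by 1.81 and the stress gene Trp53inp1 by 1.62. S phase rose in 8 of 30 members and G2 and M phase in 11 of 35 (14 and 22 adjusted over the list alone; adjusted p = 0.418 for both with an estimated correlation), for example Tyms (1.24). From P4 to P7 158 genes were higher and 158 lower. Pi16 rose by 1.97, Sod3 by 1.73 (SE 0.18), the basement membrane collagen Col4a5 by 1.62 and Adamtsl2 by 1.62, while Ube2c, Cdk1, Cdca3, Cdc20 and Pbk of mitosis fell by 1.20, 1.10, 1.08, 1.02 and 0.99. S phase fell in 11 of 30 (29 adjusted over the list alone; adjusted p = 0.0367 with an estimated correlation), G2 and M phase in 14 of 35 (30 adjusted over the list alone; adjusted p = 0.0744 with an estimated correlation), and matrix genes rose in 6 of 29 (9 adjusted over the list alone; adjusted p = 0.0367 with an estimated correlation), Eln at 1.29. Sums per litter gave 384 and 82 changed genes at these steps, and hearts of the 2 ages alone gave 564 and 824.

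**Figure D3:**
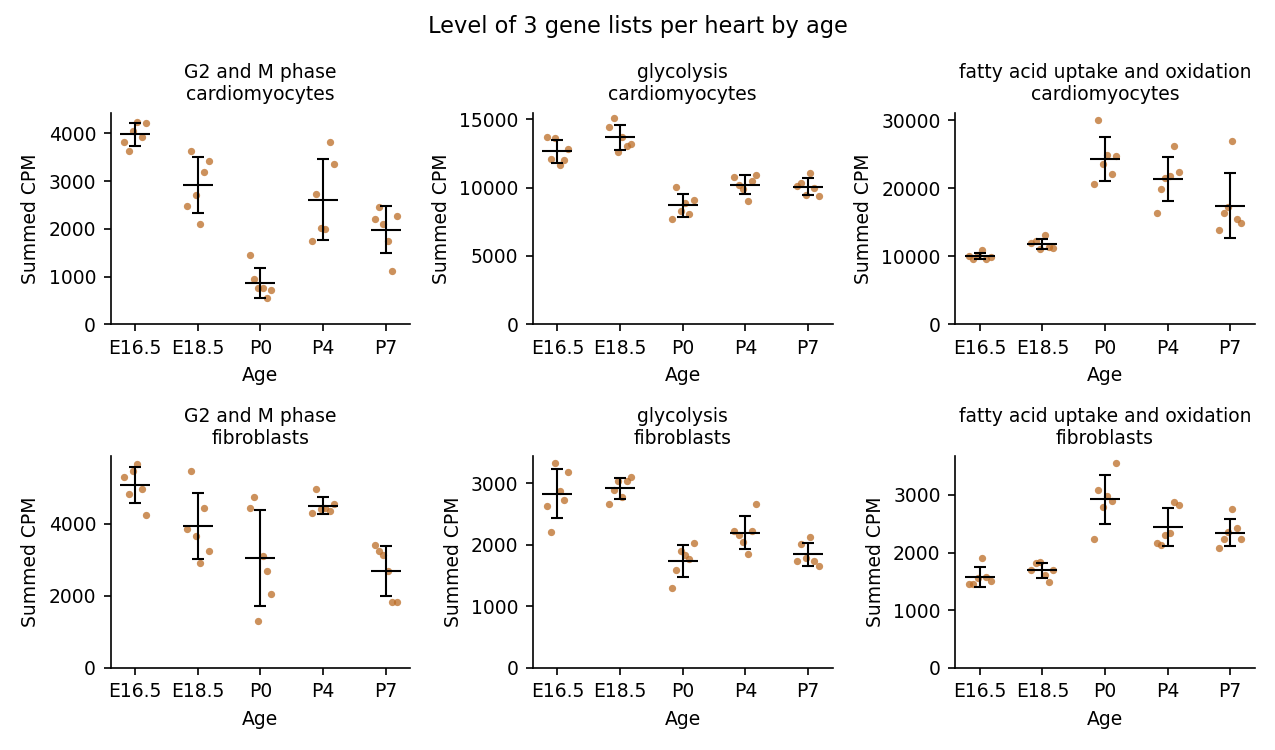
Summed CPM of the lists G2 and M phase, glycolysis, and fatty acid uptake and oxidation per heart against age in cardiomyocytes and fibroblasts, with points for single hearts and bars for mean ± SD (n = 6 hearts per age). In cardiomyocytes all 35 genes of G2 and M phase fell at P0 and rose at P4, and 24 of 29 fatty acid genes rose at P0.

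In endothelial cells 887 genes were higher and 572 lower of 9618 tested at P7 than at E16.5. Car4, the carbonic anhydrase of capillary walls, had 466 UMIs at P7 and 0 at E16.5, so it was at least 153-fold higher against a floor of 3 counts over the group. The capillary genes Ly6c1 and Ly6a rose by 4.05 (SE 0.32, adjusted p = 4.26e-12) and 3.67 (SE 0.32), the nucleoside transporter Slc28a2 by 4.13, the interferon-induced Sp100 by 4.11, Igfbp7 by 3.64, the chemokine Cxcl12 by 3.64, C1qtnf9 by 3.36, Clic5 by 3.26 and Angptl4 by 3.17. Igf2bp1 fell by 5.80 (SE 0.39, adjusted p = 8.95e-14), the solute carrier Slc22a23 by 3.21, the collagens Col13a1 and Col23a1 by 3.08 and 1.84, and the cell cycle inhibitor Cdkn1c by 3.06. Pla2g7 fell by 2.74 and Bex4 by 2.33. The hyaluronan link protein Hapln1 fell by 2.28, Clca3a1 by 2.27 and the kinase Nrk by 2.16. Vascular cells alone gave 394 higher and 274 lower genes, among them all 10 named genes that rose, and endocardial cells alone 277 and 124. Igf2bp1 fell in both labels (-5.36 and -7.34), as did Cdkn1c (-1.24 and -2.55), whereas Clca3a1 was -0.66 in vascular cells (adjusted p = 0.334).

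Endothelial lipid handling rose in 13 of 14 members (13 adjusted over the list alone; adjusted p = 0.00180 with an estimated correlation), with the fatty acid transporter Cd36 at 2.77, Fabp4 at 2.23 and the lipase anchor Gpihbp1 at 2.14, and in vascular cells alone 11 of 14 rose. Antigen presentation and interferon genes rose in 21 of 26 (22 adjusted over the list alone; adjusted p = 0.0219 with an estimated correlation), H2-D1 at 2.09. The imprinted growth network fell in 12 of 17 (14 adjusted over the list alone; adjusted p = 4.80e-05 with an estimated correlation), H19 at -1.45. Tip cell and angiogenesis genes rose in 9 of 14 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.125 with an estimated correlation), with Apln at 2.28 and Nrp2 at 1.43, whereas Plvap fell. Arterial genes rose in 5 of 14 (9 rose and 1 fell adjusted over the list alone; adjusted p = 0.0699 with an estimated correlation), and endocardium and valve genes fell in 3 of 12 (3 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). In vascular cells alone, a fit with fewer cells and genes, 1 of 11, 1 of 11 and 1 of 7 members of these 3 lists passed in those directions (medians 0.23, 0.07 and -0.11, against 0.60, 0.66 and -0.22 in the class). In endocardial cells 3 of 11 endocardium and valve genes rose. Ribosomal proteins fell in 13 of 77 (13 adjusted over the list alone; adjusted p = 0.411 with an estimated correlation; median -0.35, of the same sign under RLE scaling and without the filter). With flowcell as a block 388 genes were higher and 150 lower.

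At E18.5 33 endothelial genes were higher and 1 lower than at E16.5. Interferon genes rose in 11 of 26 members (19 adjusted over the list alone; adjusted p = 0.0111 with an estimated correlation), as for Ly6a (2.14), Isg15 (2.45) and Bst2 (1.42), and Rtp4, Ly6c1, Mgll and Ly6e rose by 2.26, 1.91, 1.39 and 1.09. Lipid handling rose in 2 of 14 (11 adjusted over the list alone; adjusted p = 0.0111 with an estimated correlation), Lpl at 1.06. Sums per litter gave 21 changed genes and the table without the filter 149.

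In endothelial cells 921 genes were higher and 860 lower at P0 than at E18.5, the most of the 4 steps, though not with flowcell as a block (242, against 603 from P0 to P4). Timp4 rose by 2.81 (SE 0.39), Angptl4 by 1.96, Setbp1 by 1.94 and the glucocorticoid-induced Klf9 by 1.91 (SE 0.27, adjusted p = 6.92e-06), as did CT010467.1, annotated as ribosomal RNA, by 2.65. Oit3 fell by 3.66 (SE 0.47), Bex4 by 1.81, Mif by 1.74, and Hells and Hmmr of dividing cells by 1.72 and 1.67. S phase fell in 26 of 30 members (27 adjusted over the list alone; adjusted p = 0.0306 with an estimated correlation), G2 and M phase in 26 of 35 (26 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation), glycolysis in 10 of 19 (10 fell and 1 rose adjusted over the list alone; adjusted p = 0.0496 with an estimated correlation), as for Pgk1 (-1.49), and the hypoxia response in 9 of 20 (9 adjusted over the list alone; adjusted p = 0.0298 with an estimated correlation), Slc2a1 at -1.82. In endocardial cells 22 of 25 S phase genes fell and in vascular cells 7 of 25. The total was 1180 without P0 replicate 1 and 953 with sums per litter.

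From P0 to P4 593 endothelial genes were higher and 561 lower. Ankrd37 rose by 2.37 (SE 0.31, adjusted p = 5.16e-06), the vessel peptide Apln by 2.32, and the replication genes Hells, Pclaf and Rrm2 by 1.94, 1.90 and 1.85, while Pla2g7, Rhou, the desmosomal Dsg2, Lbp and Corin fell by 2.19, 2.07, 2.06, 2.05 and 2.02. S phase rose in 24 of 30 (27 adjusted over the list alone; adjusted p = 0.0191 with an estimated correlation), G2 and M phase in 31 of 35 (32 adjusted over the list alone; adjusted p = 0.0631 with an estimated correlation) and glycolysis in 9 of 19 (11 adjusted over the list alone; adjusted p = 0.0456 with an estimated correlation). Tip cell genes rose in 6 of 14 (8 rose and 1 fell adjusted over the list alone; adjusted p = 0.140 with an estimated correlation), Esm1 at 2.89. Vascular cells alone gave 179 changed genes and endocardial cells 421. Tip cell genes passed in 0 of 11 members in vascular and 0 of 9 in endocardial cells (medians 0.10 and -0.06). Endocardial cells were 59.5% of the class at P0 and 24.0% at P4, so a rise of tip cell genes within a label is not shown. In vascular cells S phase rose in 4 of 25, G2 and M phase in 4 of 32 and glycolysis in 1 of 18. In endocardial cells these lists rose in 15 of 25, 26 of 34 and 8 of 15. From P4 to P7 edgeR called 0 genes higher and 1 lower in endothelial cells, with 726 genes at an unadjusted p below 0.05, against 1 and 2 by DESeq2 and 0 and 1 by limma.

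Epicardial cells, the outer covering of the heart, had 235 genes higher and 183 lower of 3075 at P7 than at E16.5. The imprinted H19, Dlk1 and Igf2 fell by 5.45 (SE 0.33, adjusted p = 9.89e-17), 4.95 (SE 0.34) and 4.32 (SE 0.50), and Clca3a1 and Nrk by 2.14 and 1.92. Complement C3 rose by 5.71 (SE 0.45) and Plet1 by 4.41 (SE 0.95), and the ion transport regulator Fxyd3 (91 and 1 UMIs, ratio 128, interval 22.4 to 5101), the complement protease C1s1 (88 and 2, ratio 61.8, interval 16.6 to 518) and Podn (40 and 1, ratio 56.2, interval 9.52 to 2273) were higher too. The imprinted growth network fell in 10 of 15 members (11 adjusted over the list alone; adjusted p = 3.25e-04 with an estimated correlation), and epicardial markers rose in 5 of 10 (7 adjusted over the list alone; adjusted p = 0.109 with an estimated correlation), Msln at 1.70. Antigen presentation genes rose in 5 of 9 (5 adjusted over the list alone; adjusted p = 0.0619 with an estimated correlation), H2-K1 among them, and ribosomal proteins fell in 38 of 77 (52 adjusted over the list alone; adjusted p = 0.144 with an estimated correlation; median -0.55, of the same sign under RLE scaling and without the filter). With flowcell as a block 103 genes changed.

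Mural cells, the smooth muscle and pericytes of the vessel wall, had 434 genes higher and 313 lower of 4923. Mural markers rose in 10 of 11 members (11 adjusted over the list alone; adjusted p = 1.08e-05 with an estimated correlation), with the smooth muscle myosin Myh11 at 3.23, Rgs5 at 2.09 and Acta2 at 1.41, and the adhesion protein Vtn, with 140 UMIs at P7 and 0 at E16.5, was at least 60.7-fold higher against a floor of 3 counts over the group. Pcp4l1, Sncg and the olfactory receptor Olfr78 rose by 6.79 (SE 0.43, adjusted p = 2.31e-16), 5.90 and 5.04, and Itih4 had 123 and 1 UMIs (ratio 160, interval 28.2 to 6367). Dlk1, H19, Cdkn1c, Igf2bp1 and Igf2 fell by 4.06, 3.54, 3.48, 3.47 and 3.11, and the imprinted growth network fell in 12 of 15 members (13 adjusted over the list alone; adjusted p = 8.69e-07 with an estimated correlation). Ribosomal proteins fell in 49 of 77 (69 adjusted over the list alone; adjusted p = 0.0873 with an estimated correlation; median -0.61, of the same sign under RLE scaling and without the filter). Flowcell as a block gave 231 changed genes.

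Macrophages had 29 genes higher and 30 lower of 2748. The scavenger receptor Cd163, a marker of resident macrophages, had 180 UMIs at P7 and 0 at E16.5, at least 16.6-fold higher against a floor of 3 counts over the group, and the chemokine receptor Ccr7 had 164 and 0, at least 15.1-fold higher. Cbr2 rose by 4.28 (SE 0.65, adjusted p = 7.80e-05), Ms4a4b by 4.09 and Ighm by 2.81. The apolipoprotein Apoc1 fell by 4.48 (SE 0.55, adjusted p = 1.07e-06), and Thbs1, the cytokine Il1a, Jdp2 and Phlda1 by 2.13, 2.09, 1.94 and 1.40. In cells labelled CCR2-low macrophages alone, 31 genes were higher and 37 lower, and all of these genes passed except Ccr7 and Ms4a4b, which were too low to be tested there. The class also holds the 448 cells labelled CCR2-high, which lymphocyte genes lead, so Ccr7 and Ms4a4b are not shown to have changed in macrophages themselves. Nor is Ighm, an immunoglobulin gene of B cells, although it passed in CCR2-low cells (2.57, adjusted p = 0.0177), since the share of B cells rose over the same ages. Resident macrophage genes rose in 3 of 10 members (7 adjusted over the list alone; adjusted p = 0.0816 with an estimated correlation), Mrc1 at 0.98, and the 5 tested genes of the MHC class II list did not pass as a list (adjusted p = 0.978). The total of 59 genes was 38 without E16.5 replicate 5, 10 with flowcell as a block and 208 without the filter.

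A further comparison asks which changes the 3 largest classes share. Between E16.5 and P7, 147 of 8478 genes tested in all 3 rose in each, against 8.13 if the classes were independent, and 144 fell in each, against 10.2. The 3 classes come from the same hearts and share free RNA. Without genes at least 5-fold more abundant in another class, 55 rose (2.16 if independent) and 102 fell (7.37) of 6820. Those that rose included the clock genes Per3 and Nr1d2, the lipid genes Lpl and Angptl4, the hormone precursor Adm and Klf9.

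Male and female hearts were compared across ages within each class. In cardiomyocytes 4 genes were higher and 3 lower in males of 10973. The Y-linked Ddx3y, Eif2s3y, Uty and Kdm5d were higher by 10.23 (SE 0.66), 8.82 (SE 0.45), 4.82 (SE 0.37) and 3.37 (SE 0.32), and Xist, the transcript of the inactive X chromosome, was lower (log2 difference -4.54, SE 0.74, adjusted p = 7.15e-04), beside the X-linked Eif2s3x (-0.71) and Vamp7 (-0.50, adjusted p = 0.0159). In fibroblasts the same 4 Y-linked genes and Xist passed, in endothelial cells these and Gm43461 (lower in males), in mural cells Ddx3y, Eif2s3y and Xist, and in epicardial cells and macrophages Ddx3y and Xist. For 1 heart, P0 replicate 1, the sex in the deposited cell table differs from the sex in its label, which leaves 15 males and 15 females by the labels and 14 and 16 by the table. This heart had 3096 UMIs of Xist and 0 of Ddx3y, while the other hearts labelled male had at most 8 and at least 269, so its expression is that of a female and goes against its label. The values above keep the label, and that of Xist rests on this heart. With the table's sex the log2 difference of Xist was -8.85 (SE 0.30) in cardiomyocytes, -8.14 in fibroblasts (-4.80 with the labels) and -8.18 in endothelial cells (-4.69). In cardiomyocytes Kdm6a and Kdm5c then passed as well, and Vamp7 did not (adjusted p = 0.123). A test of whether the change from E16.5 to P7 differed by sex in cardiomyocytes called 0 of 11961 genes in edgeR, with 685 at an unadjusted p below 0.05, 1 in DESeq2, 0 with RLE scaling and 3 without the filter.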

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

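The tests of flowcell and of P0 litter 12 behind the P0 pattern, and all tests of the cardiomyocyte share, were chosen after the result was seen; those of mitochondrial UMIs, UMIs per cell and free RNA were set before.

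Many genes changed at P0 and changed back at P4: 1073 in cardiomyocytes (488 rose and then fell, against 136 if the steps were independent, and 585 fell and then rose, against 136), 388 in fibroblasts (193 against 34.8 and 195 against 33.0) and 576 in endothelial cells (262 against 53.7 and 314 against 53.0), while 67, 17 and 23 moved the same way at both steps. The P0 hearts stand in both steps, which alone gives a negative correlation across genes (-0.53 measured and -0.47 simulated without any change in cardiomyocytes, -0.49 and -0.56 in fibroblasts, -0.56 and -0.52 in endothelial cells). The simulation called 0 genes that changed and changed back in each class, but it held no change and no effect shared by hearts of a litter or day. Few calls were possible in it, so it cannot tell whether an error shared by the P0 hearts gave the pattern. When each step used a different set of 3 P0 hearts, 451 and 474 genes (58 and 57 the same way), 61 and 58 (11 and 16) and 71 and 89 (9 and 13) were still opposite in the 3 classes. Each P0 litter has a heart in both sets, so the steps still share litters. The change of each of these genes at P0 was also taken as P0 minus the mean of E18.5 and P4. The median over genes of the percent of it left was 94.4%, 98.6% and 97.7% in the 3 classes with flowcell as a block (quartiles 73.7% to 116%, 81.9% to 114% and 79.7% to 117%). It was 94.8%, 96.1% and 101% without the 2 hearts of litter 12. With the median mitochondrial share of each heart as a covariate it was 103%, 104% and 106%. With the median UMIs per cell of each heart it was 103%, 109% and 107%. Both medians were taken over all cells of a heart, not over the class tested. The values for flowcell and for litter 12 argue against each of these as the whole cause, though with flowcell as a block far fewer genes were called at P0 in each class. Age stays in the fit, so both covariates act only through differences between hearts of the same age. They cannot decide on a shift in quality that all P0 hearts share. In all 3 classes 90 genes took part in one direction, 30 higher and 60 lower at P0, among them Klf9, Txnip, Slc16a3, Mthfd2 and Cdk1 (83 genes with the sex of the deposited table, 81 of them shared). The 90 include Xist, which is there through the sex label of P0 replicate 1 and drops out with the table's sex. The mix of labels moved as well, with atrial cardiomyocytes 1 at 11.2%, 17.8% and 13.8% of the cardiomyocytes at E18.5, P0 and P4. In ventricular cells alone 99.8% of the class calls tested there kept their direction at P0 and 99.6% at P4. Ventricular cells were 76.7%, 69.0% and 56.7% of the cardiomyocytes at these ages, so the kept direction is in part built in. Of the class calls tested there, 2137 of 2971 at P0 and 1350 of 1806 at P4 also passed in ventricular cells in the same direction. Immediate early genes, which dissociation also induces, moved with the pattern in ventricular cells, with 6 of 22 higher at P0 and 5 lower at P4. A response to birth may underlie this pattern, but the day of dissociation and the litter are nested in age and cannot be told apart from it, so it stays a hypothesis found and tested on the same data.

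The lower share of cardiomyocytes at P7 may have a technical part. A rise of fibroblasts alone would leave the ratio of cardiomyocytes to endothelial cells in place, but its log2 fell by 1.73 (exact permutation p = 0.00216). The deposited limit on mitochondrial UMIs may remove more cardiomyocytes at P7, since 10.8% of those kept had at least 12% against 4.32% at E16.5, a difference of 6.48 points (exact p = 0.0390), but the same percent was 11.7 points lower at P7 than at P0 (-11.7, exact p = 0.0173), where cardiomyocytes were 51.5% of the cells, which argues against the limit as the whole cause. The limit on UMIs per cell is not decided by the percent with at least 8000 UMIs (5.95% at P7 and 7.30% at E16.5, difference -1.35, exact p = 0.784). A poorer yield of large ventricular cells stays open, since the log2 ratio of ventricular to atrial cells changed by -2.20 (exact p = 0.00216) while median UMIs per ventricular cell changed by -1474 (exact p = 0.0844) and cells labelled atrial cardiomyocytes 1 fell too, from 8.65% to 2.48% of all cells, and so does a true change with age.

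Genes that mark cardiomyocytes also changed in the other classes, and free cardiomyocyte RNA in the droplets may account for them. Of 48 such genes called in fibroblasts 45 changed the same way in endothelial cells (93.8%, against 81.6% of the 1908 other genes called), and of 28 called in endothelial cells 26 changed the same way in fibroblasts (92.9%, against 81.8% of 920). Of the 48 genes 32 were higher at P7, and of the 28 genes 20, although the share of cardiomyocytes fell from 48.1% to 15.1%, which would lower their free RNA unless each cell gave more. A change that the classes truly share would also give a high percent, and this stays open.

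In 11 of 77 groups of 6 hearts 1 heart lay far from the others, where chance gives about 1 in 20. P0 replicate 3 had 5.03% macrophages (others 2.62% to 3.06%) and 875 cells (others 1730 to 2026). P7 replicate 1 had 1.28% valvular interstitial cells (others 0.279% to 0.546%). B cells were 0.257% in P0 replicate 1 (others 0.0494% to 0.116%) and 1.43% in P4 replicate 1 (others 0.128% to 0.469%). Neuronal cells were 0.0733% in E18.5 replicate 1 and 0.231% in P0 replicate 2, and the other 5 hearts of each age had 0. These are 1 and 4 cells, and any cell found in 1 heart alone would stand out in this way, so these 2 of the 11 groups are no sign of an unusual heart. P4 replicate 1 had 3950 median UMIs per cell (others 1929.5 to 2514) and 1725 median genes (others 1039 to 1192). Median mitochondrial UMIs were 5.86% in E18.5 replicate 2 (others 2.60% to 3.43%) and 6.01% in P4 replicate 2 (others 2.78% to 3.78%).

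The change from E18.5 to P0 differed between classes for 3 lists, by an exact permutation test of the difference per heart. The list G2 and M phase fell further in cardiomyocytes than in fibroblasts (difference of log2 changes -1.50, adjusted p = 0.00433) and endothelial cells (-1.07, adjusted p = 0.0289). Glycolysis fell further in cardiomyocytes too (-0.36, adjusted p = 0.00693, and -0.39, adjusted p = 0.00433), and the fatty acid list rose further (0.72 and 0.73, adjusted p = 0.00433 for each). For the imprinted growth network no difference was detected (0.01 and 0.11).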

How the results depend on the processing

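The fits to single labels, the fits without P0 hearts, without litter 12 or without single P0 replicates, and those with the sex of the deposited cell table were chosen after seeing the data. Unless said otherwise the values are numbers of changed genes, the cause of each shift was not tested, and fits to single labels hold fewer cells and genes. Over 18 gene counts and 280 settings, 199 counts lay within 1.5 times the reported one and 81 did not, and 3 of 108 fits without 1 heart moved as far. The 423 values of named and list genes followed here had all passed in the reported fit. Most were picked there for large changes or small p, so a high share that holds is in part built in. Of these values, 365 still passed in the same direction with flowcell as a block and 383 with sums per litter. With limma-voom 402 did, with RLE scaling 421, and with DESeq2 422 of 422. None reversed outside single labels. Of 73 list calls, 32 held with an estimated correlation and 41 did not, 68 held with fry and 72 with flowcell as a block. Small changes were recovered least in epicardial cells (44.6% of simulated 2-fold changes with edgeR), and depth and dispersion were not separated as reasons.

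With flowcell as a block, which uses up degrees of freedom in the fit, cardiomyocytes had 1633 genes (817 higher, 816 lower) at P7 against E16.5, 907 (373, 534) at P0 and 980 (558, 422) at P4, fibroblasts 1418 (853, 565) and 170 (91, 79) at P0, and endothelial cells 538 (388, 150), 242 (119, 123) at P0, 603 (356, 247) at P4 and 4 at P7 against P4. Epicardial cells had 103, mural cells 231 and macrophages 10. DESeq2 gave 235 in cardiomyocytes at E18.5, 290 in fibroblasts at E18.5 and 519 at P7 against P4, 53 in endothelial cells at E18.5 and 3 at P7 against P4, 94 in macrophages, and 1 for sex by age. Without the filter, with more genes tested, cardiomyocytes had 354 at E18.5 and 615 at P7 against P4, fibroblasts 389 and 491, endothelial cells 149 and 67, macrophages 208 (150, 58), and the sexes differed in 18, 12 and 24 genes in the 3 classes and in 3 by age. Sums per litter, with fewer samples, gave in cardiomyocytes 30 at E18.5, 2005 at P0, 1089 at P4 and 97 at P7 against P4, in fibroblasts 70, 545, 384 and 82, in endothelial cells 21, 953, 658 and 0, and in macrophages 37. limma-voom with litter as a random block gave 71 in cardiomyocytes at E18.5 and 162 at P7 against P4, 88, 839 and 618 in fibroblasts at E18.5, P0 and P4, and 15 in endothelial cells at E18.5. With only the hearts of the 2 ages compared, fibroblasts had 117 at E18.5, 724 at P0, 564 at P4 and 824 at P7 against P4, and endothelial cells 1078 at P0, 649 at P4 and 8 at P7 against P4. Without carried-over genes cardiomyocytes had 80 at E18.5, endothelial cells 0 at P7 against P4, the genes higher in 3 classes were 55, and 8 lists passed in cardiomyocytes and 5 in endothelial cells at P7 against P4. Without a sex term, with deeper cells or with the sex of the deposited table endothelial cells had 0 at P7 against P4, and with at least 30 cells per heart macrophages had 39. Of genes shared by 3 classes, 64 were higher and 29 lower at 2-fold or more.

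With replicate number as a block (paired by number; same-numbered residuals correlated over 0.1 in at most 4 of 6 pairs in any comparison, with means of up to 0.142, and at most 7 hearts did so best with their own number), cardiomyocytes had 200 genes at E18.5, fibroblasts 477 and endothelial cells 0 at P7 against P4, and with 6 differences the adjusted p of shares could not go below 0.0573, so these did not pass: cardiomyocytes -33.0 points, fibroblasts 32.8, macrophages 5.30, valvular interstitial cells -4.57, melanocytes 0.239, B cells 0.629 and T cells -0.0982 (adjusted p = 0.0982).

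Without all P0 hearts cardiomyocytes had 193 at E18.5 and 624 at P7 against P4, fibroblasts 543 and endothelial cells 7 at P7 against P4, and macrophages 93. Without P0 litter 12, fibroblasts had 774 and endothelial cells 1169 at P0. Cells labelled atrial cardiomyocytes 2 alone had 1069 at P7 against E16.5, 14 at E18.5, 1114 at P0, 707 at P4 and 29 at P7 against P4. Vascular cells alone had 668, 684 at P0, 179 at P4 and 5 at P7 against P4, endocardial cells alone 401, 17 at E18.5, 421 at P4 and 2 at P7 against P4, and pericytes alone 304. Leaving out 1 heart in turn gave 778 to 1621 in fibroblasts at P0 (778 without P0 replicate 1), 1180 to 1893 in endothelial cells at P0 (1180 without P0 replicate 1) and 38 to 76 in macrophages (38 without E16.5 replicate 5).

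Of the shares, endothelial cells differed by 0.660 points without blood cells and 0.0819 in deeper cells, and mural cells by 0.360 without blood cells and 0.518 with flowcell as a block, none past the threshold. With that block epicardial cells passed (-1.47, adjusted p = 0.00209), and melanocytes (0.243, adjusted p = 0.245), B cells (0.506, adjusted p = 0.245) and T cells (-0.113) did not; on the logit scale T cells did not pass (-0.858, adjusted p = 0.0873). Leaving out 1 heart gave -1.67 to 0.287 for endothelial, -0.886 to 0.466 for mural, -0.695 to -0.397 for epicardial, -0.125 to -0.0718 for T and -0.142 to -0.0949 for neuronal cells.

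With an estimated correlation the lists that passed numbered 2, 4, 6, 2 and 0 in cardiomyocytes (P7 against E16.5, then each step), 6, 0, 3, 0 and 4 in fibroblasts, 3, 3, 3, 4 and 0 in endothelial cells, 2 in epicardial cells, 4 in mural cells and 1 in macrophages. fry gave 6 in cardiomyocytes at E18.5, 10 in fibroblasts at P7 against P4, 3 in endothelial cells at E18.5 and 3 at P7 against P4, 14 in epicardial cells and 2 in macrophages.

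Among named genes, these reversed in single labels: Bmp10 at P7 against E16.5 in ventricular cells (-2.73), Tnnt1 at E18.5 (0.52) and Sdha at P7 against P4 (0.054) in atrial cardiomyocytes 2, Hey1 in vascular cells (-0.145), and Dll4 (-1.21), Kdr (-0.25) and Ednrb (0.081) in endocardial cells.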

Other observations

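All tests in this part were chosen after the data were seen, except the regroupings of hearts and the test of fetal cardiac isoforms and stress genes.

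Within cells labelled atrial cardiomyocytes 2, the change from E16.5 to P7 took in 522 genes higher and 547 lower of 5934, with calcium handling and ion channels higher in 14 of 21 members and fatty acid genes in 7 of 25. All cell cycle members that passed fell there, 1 of 18 in S phase and 5 of 31 in G2 and M phase, and at P0 30 of 31 members of the latter list fell and 14 of 25 fatty acid genes rose. Ribosomal proteins fell in 45 of 77 members in these cells, with a median of -0.56. In smooth muscle cells 442 genes were higher and 314 lower between E16.5 and P7, and 167 and 137 in pericytes. Mural markers rose in 6 of 9 and 7 of 9 members there, and the imprinted growth network fell in 11 of 14 and 8 of 13.

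In cells labelled CCR2-low macrophages 15 genes were higher and 6 lower at P0 than at E18.5, and 6 higher and 4 lower at P4 than at P0. Fetal cardiac isoforms and stress genes moved both ways in cardiomyocytes between E16.5 and P7, with 6 of 17 higher and 5 lower, and did not pass as a list (adjusted p = 0.794).

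Regrouping the hearts of each comparison, with 40 splits counted and the real one among them, asks whether chance can give as many genes. In cardiomyocytes 1 split (the real one) gave as many at each comparison, the least that 40 splits allow (3195 genes at P7 against E16.5 and 870 in the highest other split, 121 and 5 at E18.5, 3136 and 1870 at P0, 1904 and 860 at P4, 400 and 14 at P7 against P4). The same held in fibroblasts (2681 and 558, 183 and 14, 1440 and 959, 935 and 202, 316 and 1), in endothelial cells (1459 and 159, 34 and 9, 1781 and 881, 1154 and 97), in epicardial cells (418 and 65), mural cells (747 and 161) and macrophages (59 and 2), for sex in cardiomyocytes (7 and 0), fibroblasts (5 and 1) and endothelial cells (6 and 1), and for the genes higher (147 and 8) or lower (144 and 8) in 3 classes. For the 1 endothelial gene at P7 against P4, 3 splits gave as many (highest other 1), so chance was not excluded. The highest other splits mostly exchanged 1 heart each way and so keep most of the real grouping. The splits also break up litters, which are nested in age, so differences between litters or days were not tested.

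For the number of lists that passed with the preset correlation, chance was not excluded, because regrouped hearts also passed many lists. In cardiomyocytes the splits that gave as many were 2 at P7 against E16.5 (16 lists and 16 in the highest other), 1 at E18.5 (14 and 13), 7 at P0 (12 and 14), 4 at P4 (11 and 12) and 2 at P7 against P4 (13 and 14). In fibroblasts they were 3 (15 and 17), 1 (14 and 13), 1 (15 and 13), 5 (12 and 13) and 1 (16 and 15), and in endothelial cells 1 (17 and 16), 1 (13 and 12), 5 (13 and 13), 16 (9 and 15) and 11 (12 and 15). In epicardial cells, mural cells and macrophages they were 4 (9 and 10), 2 (16 and 18) and 3 (10 and 12). Where 1 split (the real one) alone gave as many, which is the least possible, it led the highest other only narrowly (15 and 13 at the widest). Chance was therefore not excluded there either. These outcomes lie near the limit, and an earlier, larger draw of splits gave the same outcome for every gene count but not for every list count. Calls of single lists with the preset correlation come from the same test and share this limit. Of 73 such calls, 41 were lost with an estimated correlation.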
